A study of Zea mays subsp. mays with 2 samples.

How the data were processed

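Shoots and roots of maize B73, the inbred line behind the maize reference genome, were collected separately 14 days after germination, and polyadenylated RNA of each tissue was sequenced as 1 paired-end library of 100 cycles, per the labels' protocols. The library kit did not record the strand of the RNA, and the deposited table gives no strand. Which loci are antisense transcripts therefore cannot be told here, also where several loci share a position. The series is about noncoding RNA, but the deposited table has no column that tells coding from noncoding loci, and that comparison was not made.

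The deposited values are FPKM, fragment counts scaled to transcript length and to the mapped fragments of the library, with 1 value per assembled locus and tissue. TopHat, Cufflinks and Cuffdiff are named in the submitters' processing notes. Their versions and settings, the treatment of reads with several genomic matches and any scaling between the libraries are not given in the sources used here. Coordinates are on B73 RefGen_v2, per the file headers, and are given as deposited. The span of a locus is its end minus its start and includes introns.

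The table listed 29674 loci with locus numbers up to 39085. The smallest value of the higher tissue was 1.00022 FPKM, so the table holds only loci above 1 FPKM in at least 1 tissue. A position was shared by several loci in 2270 cases, which took in 5100 loci. Both columns were matched to a sample by name, and 0 sample columns were left unused.

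Total counts were not used here, since the table gives none, but the depth left a trace in the low values. FPKM of loci alone at their position, with spans above 300 and below 2000 and with FPKM times span under 70, fell near whole multiples of a fixed worth per fragment. The worth was fitted as a constant divided by the span less an offset, by the mean cosine of the implied fragment number. Fractions of the true worth also give whole numbers. The largest worth in the range searched that scored at least 0.9 of the best was therefore kept, a rule set on simulated data. In shoot, 113 low loci gave a worth of 0.00884 FPKM per fragment at 1000 effective bases, with an offset of 220 bases and a mean cosine of 0.543. In root, 174 low loci gave 0.00766 FPKM, an offset of 230 bases and a mean cosine of 0.530. The highest mean cosine of 20 copies, with each value multiplied by a random factor of 0.7 to 1.4, was 0.275 in shoot and 0.239 in root. Of these loci, 56.6% in shoot and 62.1% in root came within 0.1 of a whole fragment, against 20% by chance without a fit. The worth and offset were fitted to these same loci, so the 20% understates the share by chance. At 1 FPKM and 1000 effective bases, a shoot locus then rests on about 113 fragments, if FPKM was scaled to mapped fragments alone, with an exact 95% Poisson interval of 0.824 to 1.20 FPKM. In root the same level rests on about 131 fragments, with an interval of 0.836 to 1.19 FPKM. Such intervals cover counting error only. Fragments behind the lower value of a fold were estimated from the fitted worth and the whole span, which overstates them where introns are present.

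With 1 library per tissue there is no spread between replicates, and no p-value between tissues was computed. Loci were described by log2((root FPKM + 1) / (shoot FPKM + 1)), which understates the change of low loci, and a locus was called higher in a tissue at a log2 ratio of 2, or 4-fold. A locus counted as detected at 1 FPKM. These rules, 31 gene lists and the rule for named loci were fixed before the data were examined. Under that rule, where no names are at hand, at most 2 locus identifiers in each direction are printed, and the 3 members of each list with the highest mean FPKM and the 3 loci with the highest FPKM in each tissue are given by position. The loci carry assembly numbers without gene names, and 0 of them matched the gene table at hand, which belongs to a later assembly. The 29 lists defined by gene names therefore had no members and gave no result. The 2 lists defined by genome, the plastid and the mitochondrial loci, were set against 10000 random lists of equal size matched on mean level in 20 bins. Other loci and regions, the lists of 10 longer loci included, are named by coordinates and were chosen after their values were seen.

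Clustering along the chromosomes was described with 1 entry per position, against 1000 shuffles of the loci within each chromosome, densest windows against 1000 shuffles over the whole nuclear genome, and shares per chromosome against 1000 rotations of the loci along the genome. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The list statistic, the fragment worth and the neighbour count were tested on simulated data. All 20 simulated lists of 15 loci moved down by 1 on the log2 scale fell below percentile 2.5, against 1 of 20 unmoved lists. Simulated worths of 8 and 10 came back as 7.98 and 9.98. The simulated loci had no introns and the rule for the worth was itself set on simulated data, so this is not an independent check. Alternatives covered the pseudocount, the fold and detection thresholds, the filter on low values and 2 rescalings. Others, added after seeing the data, left out short loci or loci listed at 0, summed loci at 1 position, or centred the ratios by level.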

Results

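The transcriptomes of maize shoots and roots 14 days after germination were compared at 29674 assembled loci, with 1 library per tissue and no replicates. The series asks which transcripts, noncoding ones included, the seedling organs make. The median level was 9.84 FPKM in shoot, with quartiles of 3.02 and 26.3, and 9.19 FPKM in root, with quartiles of 2.57 and 26.6. The steps of the low values placed 1 FPKM on 1000 effective bases at about 113 fragments in shoot and 131 in root. Every difference given here compares these 2 libraries, since the spread between plants was not measured.

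Most transcribed loci were shared between the organs. Of the 29674 loci, 24710 (83.3%) reached 1 FPKM in both tissues, 3042 (10.3%) in shoot alone and 1922 (6.48%) in root alone. The median level of loci above 1 FPKM in 1 tissue alone was 2.20 FPKM in shoot and 2.06 FPKM in root, though single loci were far higher. Across loci, log2(FPKM + 1) of the tissues correlated with a Pearson coefficient of 0.76 and a Spearman coefficient of 0.76. Loci are not independent replicates, and the table lists only loci above 1 FPKM in at least 1 tissue.

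Organ-biased loci were more numerous on the shoot side. At a 4-fold difference on the log2(FPKM + 1) scale, 2014 loci (6.79%) were higher in shoot and 1045 (3.52%) were higher in root. The other 26615 (89.7%) lay between, including low loci whose FPKM differed 4-fold or more without the pseudocount. A pseudocount of 0.1 gave 3235 loci higher in shoot and 1892 in root. The imbalance was larger at larger folds. At 32-fold with the pseudocount of 1, or 5 on the log2 scale, 320 loci were higher in shoot and 65 in root. Of the biased loci, 1105 higher in shoot and 617 higher in root were still at 1 FPKM or more in the other organ. The median log2 ratio of root to shoot over all loci was 0.06. Dividing the root values by 1.07, the median ratio of loci detected in both organs, gave 2094 loci higher in shoot and 955 higher in root.

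**Figure D1:**
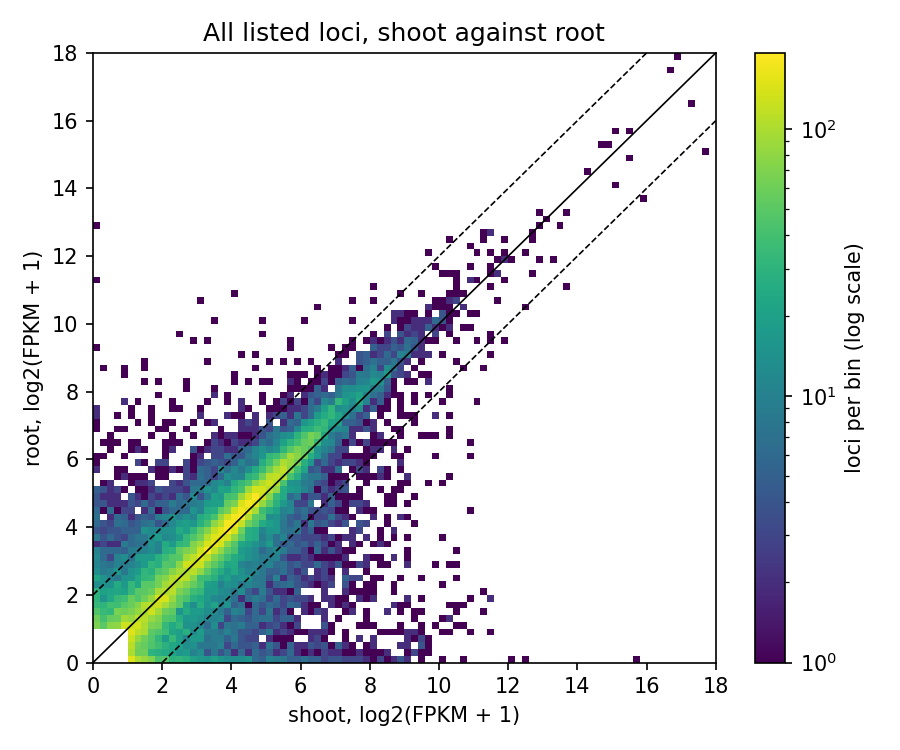
Density of the 29674 loci by log2(FPKM + 1) in shoot (horizontal axis) and root (vertical axis), with the number of loci per bin in colour on a log scale. The solid line marks equal values and the dashed lines a 4-fold difference on the log2(FPKM + 1) scale. The 2014 loci below the lower dashed line outnumber the 1045 above the upper one, and the empty corner reflects the 1 FPKM limit of the table.

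The 2 loci with the largest log2(FPKM + 1) ratios in each direction were all of about read length and listed at 0 in the other organ. XLOC_012548 on chromosome 2, from 66923039 to 66923142, was at 55825 FPKM in shoot and listed at 0 in root. XLOC_021019 on chromosome 4, from 88471764 to 88471870, was at 5466 FPKM in shoot and listed at 0 in root. On the root side, XLOC_005307 on chromosome 1, from 168413570 to 168413675, was at 7807 FPKM and listed at 0 in shoot. XLOC_025379 on chromosome 5, from 60138709 to 60138818, was at 2628 FPKM in root and listed at 0 in shoot. No fold is given for these loci, since a listed 0 can be a failed estimate.

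Among longer loci, the largest log2(FPKM + 1) ratios were again toward the shoot. In the nuclear genome, 23597 loci had a span above 300, a position of their own and values above 0 in both organs. The 10 of these with the largest log2(FPKM + 1) ratios toward shoot were at 694 to 2881 FPKM in shoot and at 0.102 to 2.88 FPKM in root, or 955-fold to 6805-fold without the pseudocount, the last on about 7.23 root fragments. This ranking favours abundant loci, and some outside the 10 had larger folds without the pseudocount. They lay on 8 chromosomes. The locus on chromosome 8 from 70797459 to 70798657 was at 2881 FPKM in shoot and 0.897 FPKM in root. The locus on chromosome 4 from 190052266 to 190053467 was at 1850 FPKM in shoot and 0.852 FPKM in root. On chromosome 8, the locus from 141641809 to 141642830 was at 2643 FPKM in shoot and 1.74 FPKM in root.

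The 10 longer loci ranked highest toward root in the same way were at 205 to 1869 FPKM in root and at 0.310 to 15.1 FPKM in shoot, or 112-fold to 1306-fold without the pseudocount, and here too some others had larger folds. The locus on chromosome 5 from 191910232 to 191911574 was at 405 FPKM in root and 0.310 FPKM in shoot. The locus on chromosome 10 from 1087128 to 1088830 was at 402 FPKM in root and 0.977 FPKM in shoot. The most abundant of the 10, on chromosome 1 from 74263374 to 74264425, was at 1869 FPKM in root and 15.1 FPKM in shoot, a 124-fold difference. The deposited table does not say which genes these are.

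All 15 loci of the plastid genome were higher in shoot than in root. Plastids carry the genes of part of the photosynthetic apparatus and are chloroplasts in green tissue. The summed level was 328 FPKM in shoot and 11.4 FPKM in root, but 69.0% of the shoot sum came from 3 loci with spans of 132 to 196 bases, all listed at 0 in root. These were also the 3 with the highest mean level: 65891 to 66023 at 158 FPKM, 72560 to 72710 at 36.1 FPKM and 111760 to 111956 at 31.7 FPKM in shoot. Over the 12 loci with a span above 300, the sums were 102 FPKM in shoot and 11.4 FPKM in root, a ratio of 8.96, but the locus from 5920 to 6899 held 62.0% of that root sum, and the ratio was 20.3 without it. In all, 7 of the 15 loci were 4-fold or more higher in shoot on the log2(FPKM + 1) scale. Over the 11 loci above 0 in root, shoot exceeded root by 1.996-fold to 158-fold, with a median of 15.6-fold. The largest folds are imprecise: by the fitted worth and the whole span, the 158-fold locus rested on about 4.96 root fragments, a 43.5-fold locus on 3.05 and the 15.6-fold locus on 2.20. Among longer plastid loci, picked after their values were seen, the one from 66980 to 67627 was at 26.7 FPKM in shoot and 0.297 FPKM in root. The locus from 919 to 1519 was at 30.1 FPKM in shoot and 1.43 FPKM in root, and the locus from 1646 to 5658 at 12.4 FPKM and 0.814 FPKM. The smallest ratio was at 5920 to 6899, with 14.1 FPKM in shoot and 7.05 FPKM in root. A value of 0 in root was listed for 4 loci. The median log2 ratio was -1.96, below every one of 10000 random lists of matched level, whose medians ran from -1.58 to 1.21. The median was -1.43 without the 3 short loci.

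The mitochondrial genome showed the opposite and smaller difference. Of its 14 loci, 12 were higher in root and 2 higher in shoot, and 0 reached a 4-fold difference. The summed level was 215 FPKM in shoot and 348 FPKM in root, a ratio of 1.62 toward root. The most abundant, from 400053 to 404303, shared its position with another of the 14. It was at 115 FPKM in shoot and 191 FPKM in root, 54.7% of the root sum. The locus from 419228 to 422119 was at 48.3 FPKM in shoot and 80.3 FPKM in root, and the locus from 111310 to 113678 at 17.7 FPKM and 27.6 FPKM. The largest ratio, 2.29, was at 265523 to 272420. The median log2 ratio was 0.33, at percentile 91.7 of the random lists, so the list did not stand apart from nuclear loci of its level as the plastid list did. Polyadenylated RNA was sequenced, so these values are not the organelles' full RNA output, and reads shared with nuclear copies of organelle DNA cannot be told apart.

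**Figure D2:**
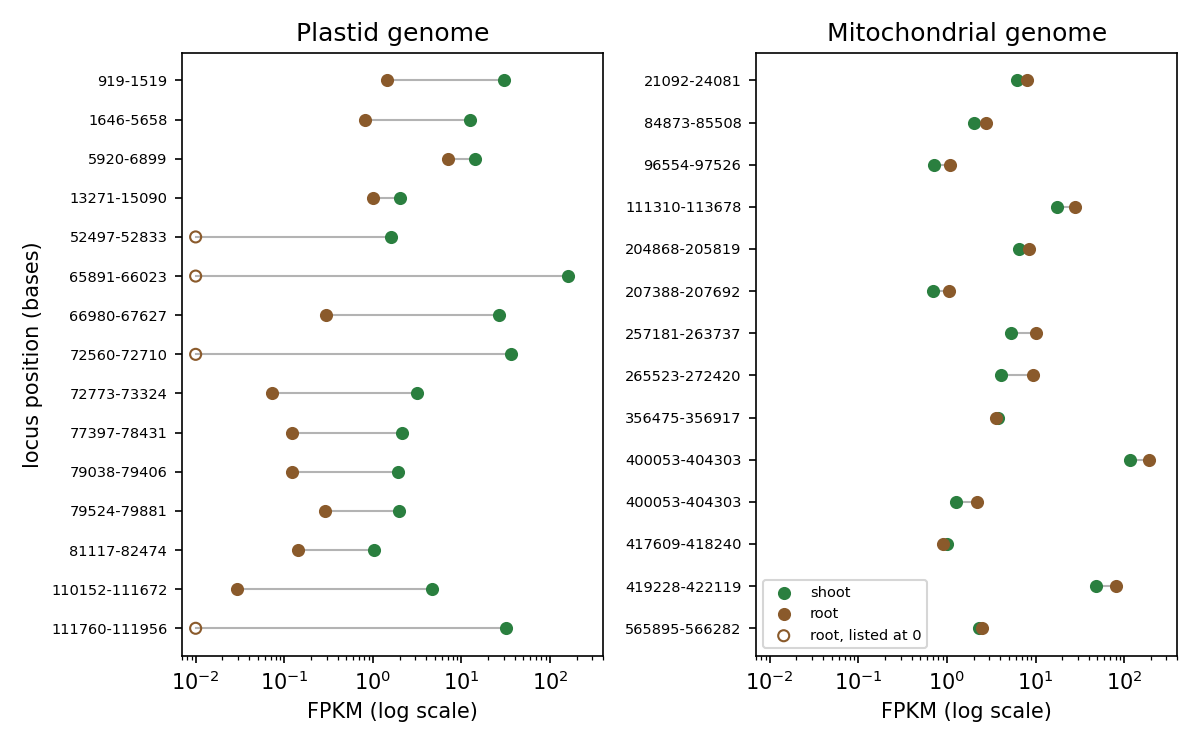
FPKM on a log axis in shoot (green) and root (brown) at the 15 plastid and 14 mitochondrial loci, ordered by position, with open circles for values listed at 0 in root and drawn at the left edge. Every plastid locus lies higher in shoot, with summed levels of 328 and 11.4 FPKM, while 12 of the 14 mitochondrial loci lie higher in root by 2.29-fold or less.

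Organ bias was spread over all 10 chromosomes. The share of loci higher in shoot ran from 5.90% on chromosome 9 to 7.29% on chromosome 2, and each of the 10 shares lay within the central 95% of rotations of the loci along the genome. The share higher in root ran from 2.64% on chromosome 8 to 4.91% on chromosome 10. Chromosome 10 lay at percentile 99.1 of the rotations and chromosome 8 at percentile 0.7, out of 10 chromosomes and both directions examined.

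Several regions held many biased loci, most of them in 1 direction. Loci in these regions were called on the log2(FPKM + 1) scale, while folds are given without the pseudocount. Between 3 and 4 Mb on chromosome 4, 10 of 27 loci were higher in shoot by this call. They were at 6.67 to 410 FPKM in shoot and 0.147 to 28.8 FPKM in root, with a median difference of 13.8-fold. Low loci there that passed 4-fold only without the pseudocount are not counted, in either direction. In this window, described after its values were seen, the locus from 3108547 to 3110776 was at 410 FPKM in shoot and 28.8 FPKM in root. The loci from 3260612 to 3262756 and from 3266077 to 3268007 were at 89.5 and 11.4 FPKM in shoot and at 1.74 and 0.147 FPKM in root. Further along, between 3.5 and 3.6 Mb, 2 loci were higher in root by the same call, at 8.18 and 43.9 FPKM against 0.0690 and 2.99 FPKM in shoot. On chromosome 2, from 10531288 to 10824400, 8 loci were higher in shoot by 8.20-fold to 631-fold, among 35 loci between 10 and 11 Mb. The 631-fold locus rested on about 5.69 root fragments at most, by its span.

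On the root side, 7 of 33 loci between 168 and 169 Mb on chromosome 7 were higher in root, by 10.6-fold to 598-fold, the last on about 2.58 shoot fragments. On chromosome 1, 6 loci within 38505 bases, from 206304263 to 206342768, were higher in root by 8.81-fold to 77.0-fold, with 3.92 to 17.9 FPKM in root. Of the 23 loci between 206 and 207 Mb there, 1 was higher in shoot, from 206263813 to 206266314, at 83.3 FPKM in shoot and 0.408 FPKM in root. On chromosome 10, 6 of 43 loci between 144 and 145 Mb were higher in root, at 13.2 to 191 FPKM in root and 1.90 to 7.02 FPKM in shoot, and 3 were higher in shoot. The largest of these 3 in level, from 144614243 to 144619550, was at 268 FPKM in shoot and 22.0 FPKM in root. These windows were among the densest of 2057 windows of 1 Mb. When the loci were shuffled over the windows, the densest window held as many shoot-biased loci in 54 of 1000 shuffles and as many root-biased loci in 71 of 1000.

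**Figure D3:**
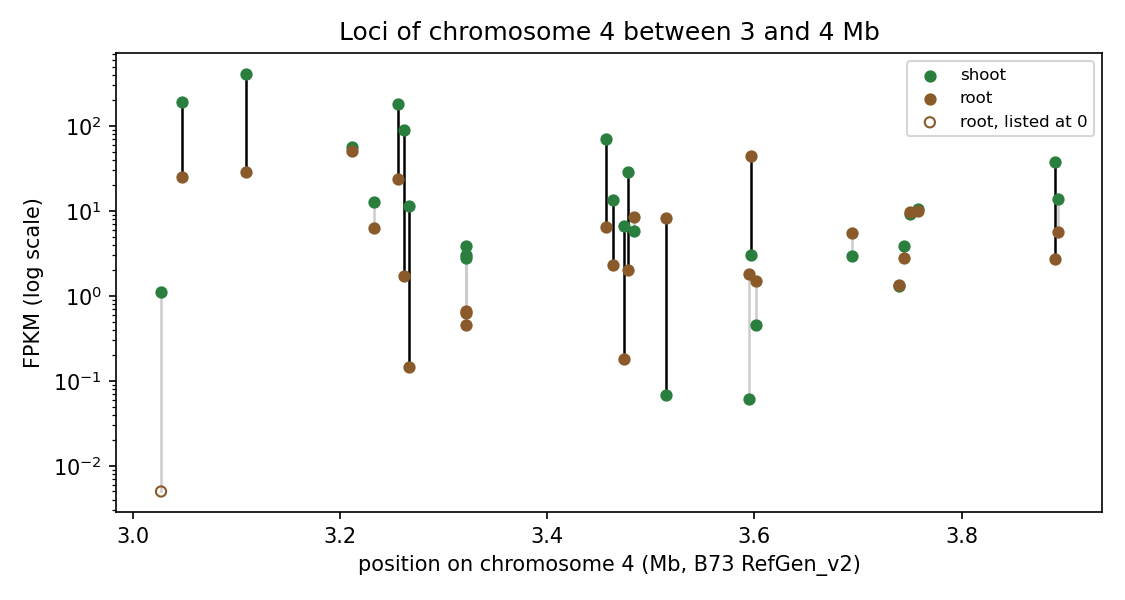
FPKM on a log axis in shoot (green) and root (brown) of the 27 loci between 3 and 4 Mb on chromosome 4, joined by a black line where they differ 4-fold or more on the log2(FPKM + 1) scale and by a grey line otherwise. The open circle is a value listed at 0 in root. All black lines between 3.0 and 3.5 Mb have the shoot value on top, and the 2 that have the root value on top lie between 3.5 and 3.6 Mb.

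Many of the highest FPKM values of both libraries came from very short loci. The highest shoot value, 220182 FPKM on chromosome 6 from 2452069 to 2452170, belonged to a locus spanning 101 bases, which was at 36842 FPKM in root. The highest root value, 234113 FPKM on chromosome 6 from 112371867 to 112372186, belonged to a locus spanning 319 bases, which was at 126508 FPKM in shoot. On chromosome 8, the locus from 18604815 to 18604916, spanning 101 bases, was at 156498 FPKM in shoot and 98130 FPKM in root. The locus on chromosome 3 from 100803594 to 100804470, spanning 876 bases, was at 109549 FPKM in shoot and 186084 FPKM in root. The 12 highest loci of the tissues had 11 members in common and made up 43.6% of the summed FPKM in shoot and 41.2% in root. Of those 12, 7 in shoot and 6 in root spanned 110 bases or less.

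Level depended on span at the short end. The 19 loci spanning 110 bases or less had a median of 11858 FPKM in shoot and 7617 FPKM in root, against 3.25 and 2.96 FPKM for the 651 loci spanning 301 to 500 bases. The 19 held 30.5% of the summed FPKM in shoot and 15.6% in root. Of the 19, 6 were 4-fold or more higher in shoot and 2 higher in root. From 111 to 150 bases, 40 of 168 loci (23.8%) were higher in shoot and 16 (9.52%) higher in root, against 6.79% and 3.52% of all loci. Spans of 150 bases or less lie below the fitted offsets of 220 and 230 bases, so the fragments behind these calls could not be estimated. Whether the larger shares reflect organ bias or counting error was not tested. Loci spanning 300 bases or less were 768 in number, 2.59% of all, and without them 1914 loci were higher in shoot and 998 in root.

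**Figure D4:**
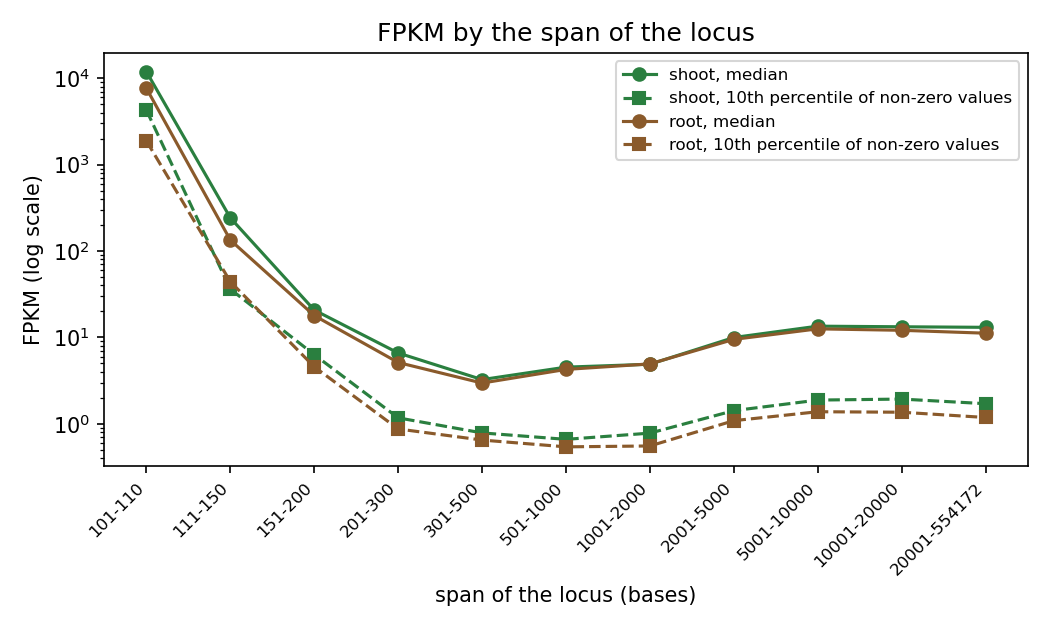
Median FPKM (circles, solid lines) and 10th percentile of non-zero FPKM (squares, dashed lines) in shoot (green) and root (brown) by the span of the locus, on a log axis. Both fall steeply from the 19 loci of 110 bases or less, with medians of 11858 and 7617 FPKM, to the class of 301 to 500 bases, with medians of 3.25 and 2.96 FPKM.

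The direction of the small differences depended on level. In the lowest 10% of loci by mean level, with medians of 1.12 FPKM in shoot and 0.848 FPKM in root, the median log2 ratio of root to shoot was -0.30. In the highest 10%, with medians of 103 FPKM in shoot and 121 FPKM in root, it was 0.30. The share of loci higher in root was largest, at 6.64%, among loci at the 30th to 40th percentile of level and was 0.674% in the lowest 10% and 2.29% in the highest 10%. The share higher in shoot was largest, at 9.27%, at the 20th to 30th percentile and was 1.52% in the lowest 10% and 4.82% in the highest. At low level the pseudocount of 1 limits the ratio a locus can reach.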

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

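The excess of loci higher in shoot over those higher in root held under all 12 alternatives, with shoot taking 55.8% to 73.2% of the calls. The counts themselves followed the threshold and the pseudocount. A pseudocount of 0.1 gave 3235 loci higher in shoot and 1892 in root, and one of 5 gave 1071 and 415. A fold threshold of 2 gave 4446 and 3520, and one of 8 gave 1038 and 380. The other 8 alternatives stayed within 1.5 times of the counts reported: shoot from 1453 to 2094 and root from 809 to 1101, the lowest with each library rescaled to a sum of 1000000. Dropping the filter on low values added no locus, since the table had been filtered at the same level. With detection at 0.1 FPKM, 714 of the listed loci were detected in shoot alone and 329 in root alone. Loci that reach only 0.1 to 1 FPKM are not listed, so these are not full counts at that level. At 5 FPKM root alone held 2000 and shoot alone 2642. The plastid median log2 ratio was -4.09 with a pseudocount of 0.1, -1.25 with sums of 1000000, -1.43 without spans of 300 or less and -1.47 without loci listed at 0, and it was below all 2000 random lists each time. The mitochondrial median was 0.54 with a pseudocount of 0.1 and 0.25 to 0.38 otherwise. Omitting short or 0-listed loci, summing shared positions and centring by level were chosen after seeing the data. The planned sums over transcripts of a gene and the comparison of coding with noncoding loci were not run, because the table has neither transcripts nor classes. No paired analysis was possible because each tissue has 1 library. No library could be left out for the same reason, and the spread between plants stays unknown.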

Other observations

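Loci biased toward the same organ lay side by side along the chromosomes more often than in shuffled orders, though most had no such neighbour. With 1 entry per position, 1021 positions were 4-fold or more higher in root on the log2(FPKM + 1) scale and 1957 higher in shoot. For root, 121 pairs of neighbours were both higher, against a mean of 39.7 and a highest value of 61 in 1000 shuffles. For shoot, 198 pairs were both higher, against a mean of 143 and a highest value of 177. At gaps of 100000 bases or more no excess was seen for shoot, with 31 pairs against a mean of 33.0 and 653 of 1000 shuffles as large, while root had 23 pairs against a mean of 9.42 and a highest value of 22. Whether the excess differs between the organs was not tested. On chromosome 7, 4 of the root-biased loci from 168807255 to 168995258 had spans of 1434, 1437, 1429 and 1434 bases, and were at 14.4, 11.2, 5.05 and 12.5 FPKM in root and at 0.0856, 0.0187, 0.0230 and 0.230 FPKM in shoot. On chromosome 4, the genes of benzoxazinoid synthesis, which make defence compounds of maize, are known to cluster on the short arm. Whether the 10 shoot-biased loci between 3 and 4 Mb include them was not tested, since no annotation of this assembly was used here.

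The tests on short loci and on the spans of neighbours were chosen only after the result was seen, the span test once the near-equal spans on chromosome 7 had been noticed. Pairs of neighbours 10000 bases or more apart were both higher in root 90 times, against a highest value of 45 in the shuffles. By the rule written beforehand, this count spoke against a single transcript broken into several loci. That rule took the pieces of 1 transcript to lie less than 10000 bases apart. However, 2592 loci spanned 10001 to 20000 bases and 1737 spanned more. A broken transcript could therefore leave such gaps, and the count cannot decide. The test did not cover closer root-biased pairs, 9 at gaps under 1000 bases and 22 at 1000 to 10000 bases. A broken transcript stays open for the closer and the farther pairs. A candidate explanation is tandem copies of 1 gene with shared root expression. Of the 121 pairs, 25.6% had spans within 10% of each other, against a median of 7.44% and a highest value of 15.7% in 1000 sets of random pairs of root-biased loci. Without the window that prompted the test 30 of 120 pairs had such spans, but that window held too few of the 121 pairs to change the share. Among 21283 pairs of neighbours without bias the share was 6.91%. Sequences of the 121 pairs were not compared, so reads shared between such copies stay open, and they may make 1 active copy look like several.

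For the shoot-biased neighbours, 130 pairs lay 10000 bases or more apart, equal to the highest of the shuffles, and 1 of 1000 shuffles was as large. By the rule written beforehand this count would have fitted a transcript broken into several loci, and the label was changed to undecided once the count was seen. Spans were near-equal in 9.09% of the shoot-biased pairs, against a highest value of 12.1% in random pairs, with 44 of 1000 sets as large, so tandem copies were not settled either.

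The very high FPKM of short loci stays without an explanation that these tables decide. FPKM is divided by an effective length, and where that length is near 0 a few fragments give a large value. The 10th percentile of non-zero shoot FPKM was 4254 at spans of 110 or less and 0.785 at spans of 301 to 500, a ratio of 5418, but this restates the pattern, and abundant short RNAs would give the same value. Of the 19 shortest loci, 14 were at 1000 FPKM or more in both organs. The number of fragments behind them is not known, so an effective length near 0 and real abundance cannot be told apart.

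Values of exactly 0 were listed for 213 loci in root and 92 in shoot. Among loci with a span above 300 and 100 FPKM or more in 1 organ, 5 were at exactly 0 in the other organ and 3 were above 0 but worth under 3 fragments, too few to settle whether a listed 0 was a failed estimate. By the rule written beforehand, 5 against 3 would have fitted a failed estimate, and the binomial margin (p = 0.727) was added after these counts were seen. On chromosome 7, all 3 loci at 4307324 to 4373654 were listed at 0 in root and at 4103, 498 and 21.5 FPKM in shoot. Those at 4103 and 498 FPKM were both among the 5, so the 5 are not independent, as the binomial margin assumes them to be. At the position on chromosome 1 from 210841642 to 210848854, 1 locus was at 445 FPKM in shoot and listed at 0 in root, while the other was at 38.0 FPKM in shoot and 6.60 FPKM in root. Opposite 4-fold biases at 1 shared position were found at 4 of the 2270 shared positions.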
